A study of Drosophila melanogaster with 15 samples.

How the data were processed

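Total RNA from wing imaginal discs of Drosophila melanogaster was labelled with biotin, starting from 200 ng per sample, and hybridized to Affymetrix 1-colour arrays, per the labels. Discs came from staged larvae at 92, 116 or 168 h after egg deposition. In the knockdown larvae rn-GAL4 drove an RNAi construct against avl, the gene now named Syx7, which encodes the early endosomal syntaxin 7. Control larvae carried rn-GAL4 alone, and both genotypes carried elav-GAL80. The 15 arrays formed 5 groups of 3 (control at 92 and 116 h, avl-RNAi at 92, 116 and 168 h). Groups were taken from the labels.

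The deposited table held log2 values of 18952 probe sets, already normalized between arrays by the authors. Every array had the same mean (6.01) and nearly the same median (4.74 to 4.79). The log base was inferred from the range of the values, and Partek and limma were named in the submitters' notes without a role or version. The background correction and the normalization method were not stated. The values were used as deposited. Arrays give no read depth, so the number of arrays limits the precision.

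The platform annotation gave 1 gene symbol for 13647 probe sets, several for 402 and none for 4903, of which 183 were control probe sets. Symbols were updated through the gene identifier for 13544 probe sets, and 103 kept the annotation's symbol. A gene was represented by its probe set with the highest mean value over the 15 arrays, which gave 11982 genes; 1094 genes had several probe sets. Probe sets with several symbols or none were left out of the gene-level tests and counted apart. Cuticle protein, glutathione transferase, Jonah protease and ribosomal protein genes belong to families of similar sequence, so their probe sets can respond to related members.

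Genes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, on all 15 arrays with a mean for each of the 5 groups and 10 residual degrees of freedom. Moderated tests were 2-sided, with Benjamini-Hochberg adjustment over the genes of each of 7 comparisons. A gene was called, and is described as having risen or fallen, at adjusted p under 0.05. Counts of genes that were called and changed at least 2-fold (a log2 difference of 1 or more in size) are given beside. Differences are in log2 units with their standard errors, for 3 arrays per group. The 7 comparisons were avl-RNAi against control at 92 h and at 116 h, the difference between these (the interaction of genotype and age), 116 h against 92 h in each genotype, avl-RNAi at 168 h against avl-RNAi at 116 h, and avl-RNAi at 168 h against control at 116 h.

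The comparisons, the tests, 28 gene lists and the rule for named genes were fixed before the data were examined. The rule took Ilp8, puc, Syx7, Mmp1 and upd3 always. For the comparisons at 92 h and 116 h it took the 10 largest rises and the 10 largest falls among called genes whose 3 arrays of 1 group all lay above the 3 of the other, leaving out genes known only by a number. For each other comparison it took 5 of each. From each list it took up to 4 members with the smallest adjusted p. Syx7, Mmp1 and upd3 had no probe set with a symbol of their own in the annotation and were not analysed here. The lists were tested with camera (preset correlation 0.01), adjusted over the 28 lists of a comparison. Camera with an estimated correlation and fry were run beside it. Lists overlap, so they are not independent. Camera counts how far a list's members lie from the other genes, and a called list can hold members that moved either way.

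The overlap of the differences at 92 h and 116 h was compared with the count that independent lists would give. These comparisons share no array, and neither do the ageing comparisons of control and avl-RNAi discs. Correlations between comparisons are across genes, which are not independent replicates. The design could recover known changes when tested on simulated data, in which 200 genes per run were shifted. Of 2-fold changes 95.4% to 98.8% were recovered, depending on the comparison, and of changes of 0.5 on the log2 scale 61.4% to 85.2%. Between 4.37% and 5.25% of the calls were false. The simulated noise was drawn for each gene independently, without RNA of other tissues that shifts many genes together. These rates therefore need not hold for the real arrays.

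The alternatives planned were the arrays of the compared groups alone, the replicate number as a block, a trended and robust prior, array weights, quantile normalization, median centring, leaving out the lowest 25% or 50% of genes by mean value, the mean of a gene's probe sets, adjusted p under 0.01, and leaving out each array in turn. Replicate numbers were not taken to pair the samples. Correlations between same-numbered arrays of different groups were computed on deviations from the group means. They ranged from -0.41 to 0.50, and 9 of 30 exceeded 0.1. Control and avl-RNAi discs at 92 h gave 0.50 for replicate 1 and 0.38 for replicate 3, so a shared preparation of some arrays is not excluded. Lists of gut, muscle and fat body genes (17, 10 and 6 genes) were drawn up after the data were seen. Their mean values per array served as covariates in added alternatives, and the control arrays at 92 h replicate 3 and 116 h replicate 2, unusual in their gut transcripts, were left out together in another.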

Results

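Gene expression was measured in wing imaginal discs, the larval epithelia that form the wing and notum of the fly. The labels describe discs with avl knockdown as neoplastic and control discs as wild type. Control discs were sampled at 92 and 116 h after egg deposition and avl-RNAi discs at 92, 116 and 168 h, with 3 arrays per group. Correlations of whole arrays were 0.994 to 0.998 within groups and 0.970 to 0.996 between groups. The knockdown itself could not be read from these values, because Syx7 had no named probe set. Mmp1 and upd3 were also not analysed here, for the same reason.

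Transcripts of other larval tissues varied between the arrays. The mean of 17 gut protease and lysozyme genes was 7.10 and 7.09 in control 92 h replicates 1 and 2 but 4.96 in replicate 3. It was 6.96 in control 116 h replicate 2 but 4.88 and 4.77 in replicates 1 and 3. It lay between 6.19 and 7.20 at 92 h, 5.19 and 5.32 at 116 h, and 4.54 and 4.68 at 168 h in avl-RNAi discs. The mean of 10 muscle genes was 8.48 ± 0.25 (SD, n = 3) in control and 9.22 ± 0.28 in avl-RNAi discs at 92 h, 6.81 ± 0.46 and 7.94 ± 0.35 at 116 h, and 5.65 ± 0.19 in avl-RNAi discs at 168 h. The mean of 6 fat body genes was 9.50 ± 0.47 in control and 9.82 ± 1.07 in avl-RNAi discs at 92 h, 8.50 ± 0.99 and 9.94 ± 0.79 at 116 h, and 7.75 ± 0.30 in avl-RNAi discs at 168 h. Genes that change with age followed the labels in the 2 control arrays with unusual gut transcripts, with ImpE2 at 4.74 in control 92 h replicate 3 and 13.35 in control 116 h replicate 2.

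**Figure D1:**
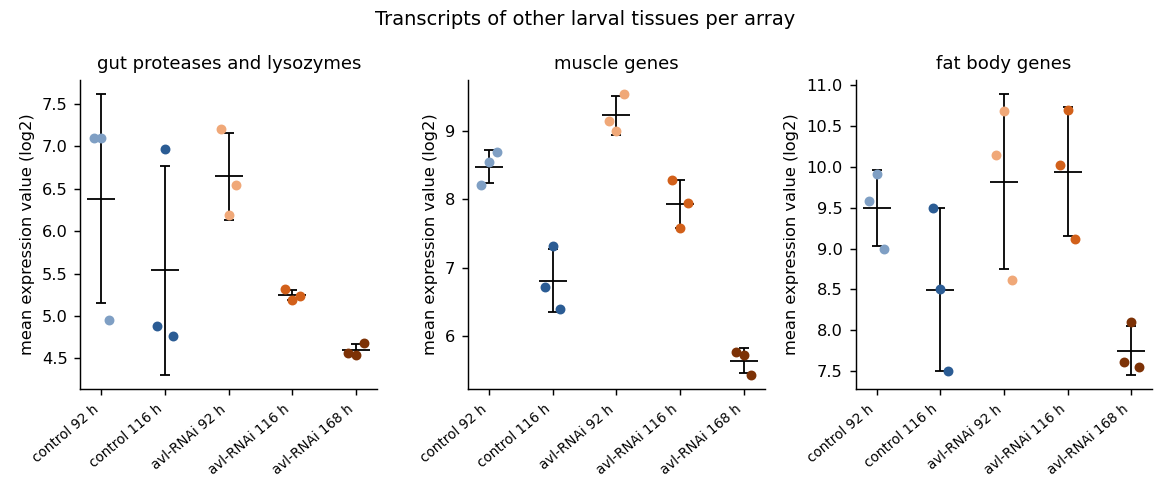
Mean log2 expression value of 17 gut protease and lysozyme genes, 10 muscle genes and 6 fat body genes in each array (points), with the group mean and SD (bars, n = 3). Control 92 h replicate 3 (4.96) and control 116 h replicate 2 (6.96) lay apart from their groups in gut transcripts, and muscle transcripts were lower in older discs of either genotype.

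At 92 h the question was how avl-RNAi discs differed from control discs during the third instar. Several larval cuticle genes were higher in avl-RNAi discs, led by Lcp65Ac (2.60 ± 0.20, 6.08-fold), Cpr47Eg (2.01 ± 0.23), Lcp9 (1.85 ± 0.47), Lcp65Ae (1.56 ± 0.15) and Lcp65Ag3 (1.43 ± 0.19). Ilp8, which encodes the relaxin-like peptide that damaged or overgrowing discs secrete to delay metamorphosis, was already higher by 1.49 ± 0.16 (2.81-fold, adjusted p = 9.32e-05, all 3 avl-RNAi arrays above all 3 controls). The JNK phosphatase gene puc showed 0.05 ± 0.10 and did not pass the test (adjusted p = 0.871). The antimicrobial peptide genes Mtk (-1.51 ± 0.24), DptB (-0.94 ± 0.23) and Def (-0.67 ± 0.17) were lower, while most innate immune genes measured were not called.

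The other large rises at 92 h were mthl8 (1.83 ± 0.096), a methuselah-like receptor gene, swi2 (1.58 ± 0.065), l(3)mbn (1.54 ± 0.13) and pinta (1.52 ± 0.23). Beside Mtk, the largest falls were Obp46a (-1.86 ± 0.25), an odorant-binding protein gene, the gustatory receptor gene Gr64a (-1.66 ± 0.085) and the ribosomal protein gene RpS21 (-1.57 ± 0.053). Ktch (-1.48 ± 0.066), RpS19b (-1.38 ± 0.092), the kinetochore gene Mis12 (-1.36 ± 0.055), Gr64f (-1.27 ± 0.11), Pa1 (-0.97 ± 0.15) and sfl (-0.94 ± 0.054) followed. RpS21 was an abundant transcript, at 13.57 ± 0.04 in control discs at 92 h (mean ± SD). Its difference was -1.44 ± 0.053 at 116 h and -1.60 ± 0.053 between avl-RNAi discs at 168 h and controls at 116 h, and a difference this constant cannot be separated from one between the fly stocks.

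Of the 28 gene lists, 4 were called higher and 2 lower at 92 h. Among cuticle and chitin genes 20 of 131 measured members rose and 1 fell (25 and 7 adjusted over the list alone, camera adjusted p = 0.00394, 0.332 with an estimated correlation). For the JNK pathway and its reported targets 2 of 19 measured members rose and 0 fell (3 and 1 adjusted over the list alone), and the list was called higher (adjusted p = 0.0192, 0.282 with an estimated correlation). Its risers were Ilp8 and Traf4 (0.32 ± 0.077), a signalling adaptor gene whose other probe set showed -0.23. Among extracellular matrix genes 1 of 20 measured members rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.000117, 0.282 with an estimated correlation), and the riser was the peptidase gene Ance (0.46 ± 0.12). Among haemocyte markers 1 of 21 measured members rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.00394, 0.644 with an estimated correlation), and the riser was ush (0.33 ± 0.087), which discs also express in the notum. Among innate immune genes 0 of 26 measured members rose and 4 fell (0 and 4 adjusted over the list alone, camera adjusted p = 0.0216, 0.282 with an estimated correlation). Notch targets and proneural genes were called lower as a list (adjusted p = 0.00139, 0.512 with an estimated correlation), although 0 of 21 measured members rose and 0 fell (0 and 0 adjusted over the list alone).

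In all, 537 of 11982 genes were called at 92 h, 292 higher and 245 lower in avl-RNAi discs, and 2026 had an unadjusted p under 0.05. Of the called genes 38 were at least 2-fold higher and 11 at least 2-fold lower. Muscle transcripts were higher in the avl-RNAi group at this age, and gut transcripts were low in control replicate 3. The count of called genes fell to 257 without that array and control 116 h replicate 2. It fell to 351 without avl-RNAi 92 h replicate 2, 288 without control replicate 1, 349 without control replicate 2 and 290 without control replicate 3. Without control replicate 3 the calls of Lcp9, Traf4, Ance, ush, DptB and Def ended, and with the gut, muscle and fat body values as covariates 135 genes were called (87 higher and 48 lower) and those of Obp46a, Pa1 and pinta ended too.

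At 116 h, when control discs reached the end of the third instar, Ilp8 and the ligand genes upd1 and upd2 were far higher in avl-RNAi discs. Ilp8 was the largest rise, at 6.02 ± 0.16 (adjusted p = 1.52e-11), from 4.59 ± 0.077 in control, below the median of every array, to 10.61 ± 0.21 in avl-RNAi discs (mean ± SD, n = 3). The JAK/STAT ligand genes upd1 and upd2 were higher by 3.43 ± 0.11 and 3.25 ± 0.11, and chinmo, a zinc finger gene downstream of JAK/STAT that is typical of younger tissue, by 3.88 ± 0.11 (14.8-fold). The other probe sets of chinmo gave values between 0.41 and 4.11. In control discs at 116 h upd2 lay between 4.59 and 4.63, below the median of every array. Among the largest falls were the ecdysone-inducible genes ImpE2 (-5.51 ± 0.36) and ImpE3 (-3.56 ± 0.18) and the serpin genes Spn43Aa (-4.97 ± 0.23) and Spn100A (-4.37 ± 0.34).

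The remaining large rises at 116 h were Tdc1 (4.80 ± 0.12), which encodes a tyrosine decarboxylase, flap (4.0 ± 0.16), Osi14 (3.89 ± 0.14), the glutathione transferase gene GstE6 (3.78 ± 0.11), Rcd2 (3.62 ± 0.087), Tig (3.47 ± 0.27), which encodes the matrix protein tiggrin, and Ude (3.40 ± 0.15). The remaining large falls were the sulfotransferase gene St2 (-4.18 ± 0.15), nebu (-3.94 ± 0.21), wbl (-3.72 ± 0.16), ana (-3.35 ± 0.13) and the cuticle genes Cpr49Ac (-3.26 ± 0.32) and Cpr78E (-2.82 ± 0.24).

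**Figure D2:**
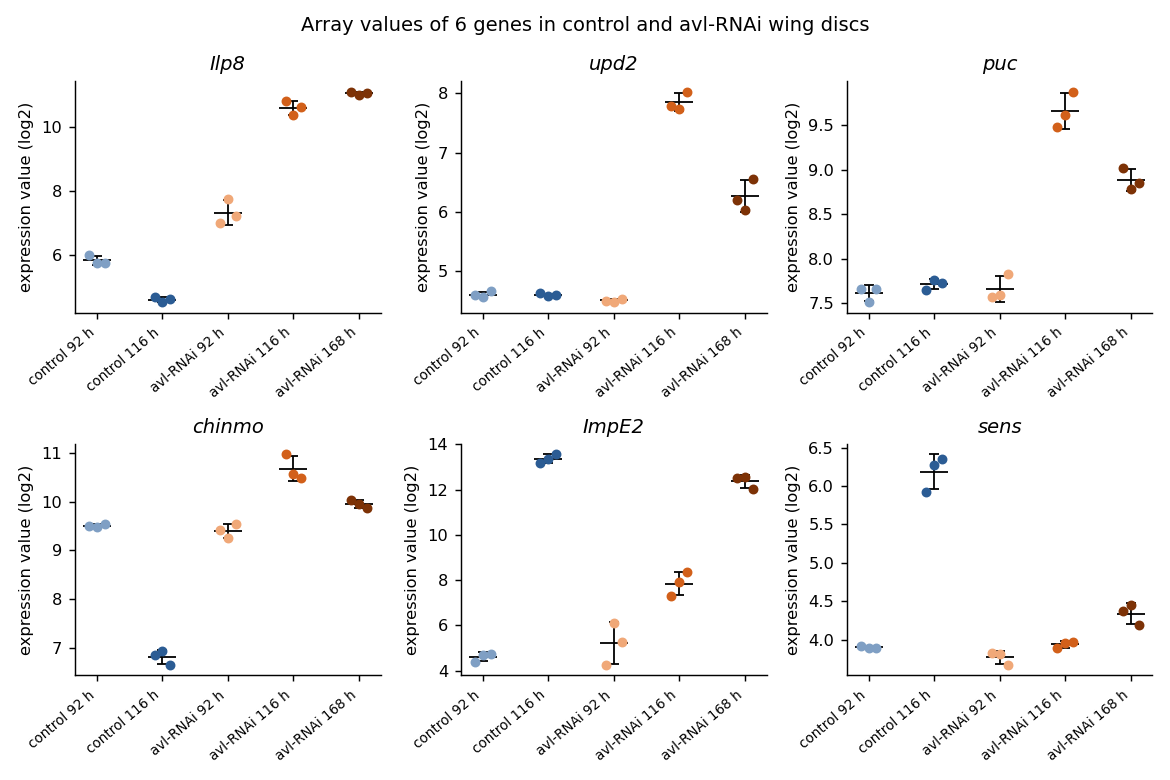
Log2 expression value of Ilp8, upd2, puc, chinmo, ImpE2 and sens in each array (points), with the group mean and SD (bars, n = 3). Ilp8 averaged 5.82 and 4.59 in control discs at 92 and 116 h and 7.31, 10.6 and 11.1 in avl-RNAi discs at 92, 116 and 168 h, whereas ImpE2 reached 13.4 in control discs at 116 h and 12.4 in avl-RNAi discs only at 168 h.

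Stress signalling lists were higher in avl-RNAi discs at 116 h. For the JNK pathway and its targets 13 of 19 measured members rose and 3 fell (13 and 4 adjusted over the list alone, camera adjusted p = 1.4e-07). Ets21C, an ETS transcription factor gene, was at 2.99 ± 0.087, the growth factor gene Pvf1 at 2.47 ± 0.11, the serine protease homologue gene scaf at 2.24 ± 0.10 and puc at 1.95 ± 0.10 (3.85-fold). For JAK/STAT 6 of 10 measured members rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 5.64e-05). The list holds chinmo, upd1, upd2 and ken (1.33 ± 0.082). Among secreted signals 10 of 26 measured members rose and 5 fell (12 and 6 adjusted over the list alone, camera adjusted p = 0.00486, 0.0821 with an estimated correlation). Among glutathione transferases and oxidative stress genes 20 of 52 measured members rose and 10 fell (22 and 10 adjusted over the list alone, camera adjusted p = 0.000199). The metallothionein gene MtnA was at 2.38 ± 0.23, GstE1 at 1.08 ± 0.099 and GstO1 at 0.73 ± 0.071. Early larval factors were called higher (adjusted p = 0.0422, 0.274 with an estimated correlation), where 2 of 5 measured members rose and 0 fell (2 and 0 adjusted over the list alone), these being chinmo and the RNA-binding protein gene Imp (0.91 ± 0.088). The 4 probe sets of Imp ranged from 0.0095 to 1.14.

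Matrix and tracheal lists were also higher at 116 h. Among extracellular matrix genes 8 of 20 measured members rose and 5 fell (10 and 6 adjusted over the list alone, camera adjusted p = 0.037, 0.445 with an estimated correlation). The risers included Tig, Swim (2.02 ± 0.22), the perlecan gene trol (0.91 ± 0.058) and SPARC (0.88 ± 0.094). The 8 probe sets of trol ranged from -0.055 to 0.91. Among tracheal markers 7 of 13 measured members rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.00626, 0.353 with an estimated correlation). Among them were apt (0.25 ± 0.064) and verm (0.77 ± 0.095), serp (0.74 ± 0.06) and Gasp (0.62 ± 0.072), which encode chitin-modifying or chitin-binding proteins.

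The 4 lists called lower at 116 h were wing pouch and hinge patterning, Notch targets and proneural genes, glycolysis, and cell cycle. For wing pouch and hinge patterning 2 of 31 measured members rose and 17 fell (3 and 18 adjusted over the list alone, camera adjusted p = 0.0012, 0.402 with an estimated correlation). The T-box genes Doc2 (-1.65 ± 0.094) and Doc3 (-1.06 ± 0.062) fell. The homeobox gene dve showed -1.52 ± 0.094, although its other probe set showed 0.0062, and Sox15 showed 0.66 ± 0.046, with -0.071 at its other probe set. For Notch targets and proneural genes 3 of 21 measured members rose and 15 fell (3 and 15 adjusted over the list alone, camera adjusted p = 0.000185, 0.287 with an estimated correlation). The falls with the smallest adjusted p were sens (-2.25 ± 0.096), the zinc finger gene of sensory organ precursors, and the proneural gene sc (-1.03 ± 0.098), Tom (-0.80 ± 0.074) and ase (-0.62 ± 0.057). For glycolysis and lactate production 0 of 13 measured members rose and 9 fell (0 and 9 adjusted over the list alone, camera adjusted p = 0.00248, 0.213 with an estimated correlation). Ldh and PyK were not among the measured members, so production of lactate was not covered. The falls included the glucose transporter gene Glut1 (-1.26 ± 0.11, with probe sets from -1.26 to -0.23), Pfk (-0.65 ± 0.09), Tpi (-0.40 ± 0.06) and Gapdh1 (-0.26 ± 0.063). For cell cycle and DNA replication 3 of 36 measured members rose and 14 fell (3 and 14 adjusted over the list alone, camera adjusted p = 0.0248, 0.488 with an estimated correlation). Its falls included E2f2 (-0.54 ± 0.039), Cdk4 (-0.45 ± 0.042), borr (-0.47 ± 0.05) and rux (-0.46 ± 0.053). The last call ended with quantile normalization and in several other settings.

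Lists that were not called at 116 h held large changes of single members. Ecdysone response genes included falls of ImpE2, ImpE3 and Eip78C (-2.28 ± 0.11) and a rise of the nuclear receptor gene ftz-f1 (2.05 ± 0.11). In this list 3 rose and 8 fell of 26 (3 and 9 adjusted over the list alone, camera adjusted p = 0.114). Among cuticle and chitin genes 25 rose and 18 fell of 131 (25 and 18 adjusted over the list alone, camera adjusted p = 0.0905). TwdlE was at 3.24 ± 0.18 and Cht6 at 2.04 ± 0.10 but Cpr65Ec at -2.32 ± 0.14. Among heat shock proteins 3 rose and 7 fell of 17 (3 and 7 adjusted over the list alone, camera adjusted p = 0.363). Hsp26 was at -2.69 ± 0.091 and Hsp27 at -1.47 ± 0.10 but the cochaperone gene stv at 1.19 ± 0.059. Among endosomal and ESCRT genes 8 rose and 9 fell of 27 (9 and 11 adjusted over the list alone, camera adjusted p = 0.757). The members with the smallest adjusted p were ALiX (0.82 ± 0.053), Vps4 (0.55 ± 0.057), Vps28 (0.35 ± 0.045) and TSG101 (0.31 ± 0.043), all higher. In the Hippo list 1 rose and 3 fell of 11 (1 and 4 adjusted over the list alone, camera adjusted p = 0.363). This list holds pathway components such as yki, wts and ds beside targets. Diap1, Myc, dally and E2f1 were not measured, so the result does not stand for the targets alone.

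**Figure D3:**
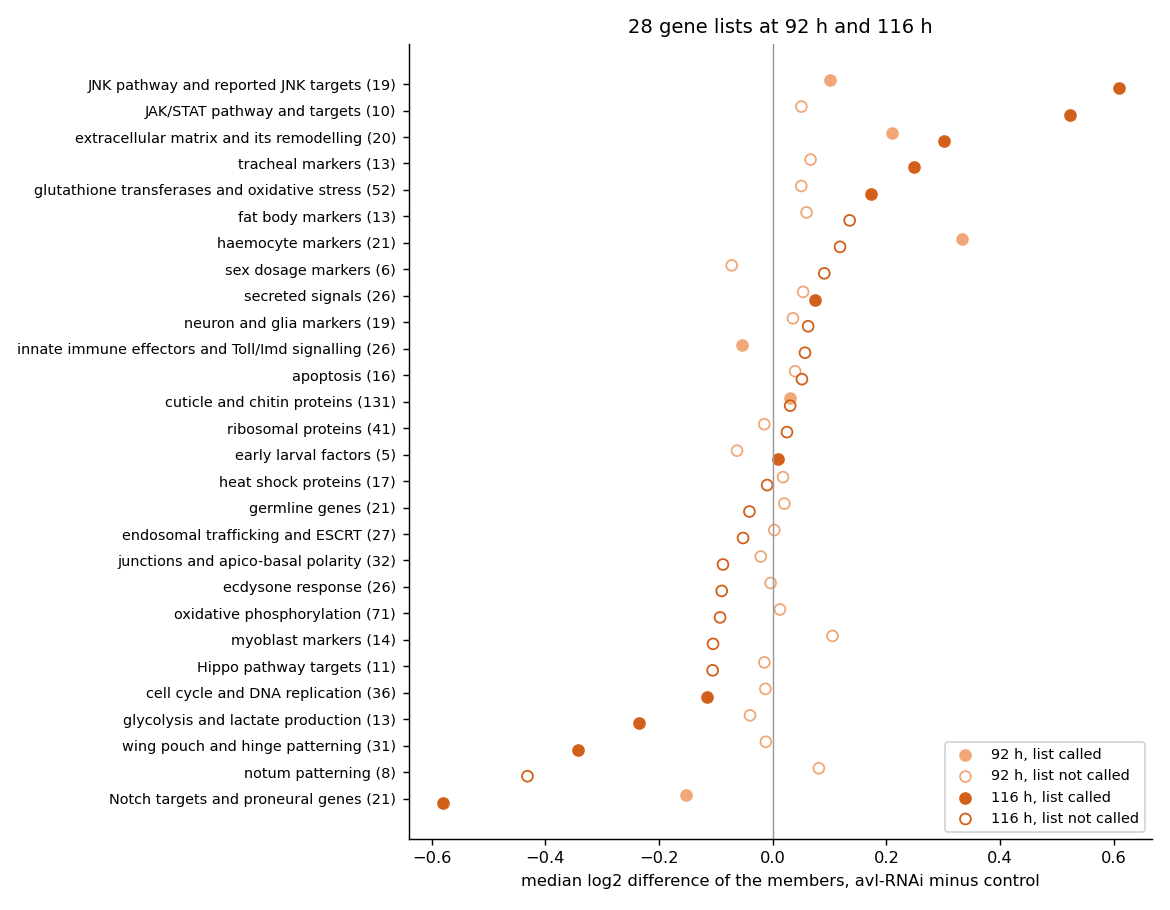
Median log2 difference, avl-RNAi minus control, of the measured members of 28 gene lists at 92 h and 116 h, with the number of members in brackets and lists called by camera at the preset correlation as filled points. At 116 h the JNK list had the highest median (0.61) and Notch targets and proneural genes the lowest (-0.58).

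In all, 3794 genes were called at 116 h, 1511 higher and 2283 lower in avl-RNAi discs, with 306 at least 2-fold higher and 163 at least 2-fold lower. Of all 11982 genes 4857 had the arrays of the groups fully apart, where chance gives 10%. Muscle and fat body transcripts were higher in the avl-RNAi group at this age, and gut transcripts were high in control replicate 2. With the gut, muscle and fat body values as covariates 688 genes were called, of which most were now higher (396 higher and 292 lower), the median standard error rose from 0.074 to 0.16, and the calls of Glut1, Pfk, Tpi, SPARC, MtnA, GstO1, Gasp, verm, apt, borr and rux ended with their direction kept.

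The interaction of genotype and age tested directly whether the avl-RNAi difference changed between 92 h and 116 h. The largest increases of the difference were in Tdc1 (4.65 ± 0.17), Ilp8 (4.53 ± 0.22), chinmo (3.99 ± 0.16), Osi14 (3.83 ± 0.20) and flap (3.69 ± 0.23). The largest decreases were in ImpE2 (-6.12 ± 0.51), Spn43Aa (-4.93 ± 0.33), Spn100A (-4.32 ± 0.48), St2 (-4.04 ± 0.21) and wbl (-3.78 ± 0.22). The JNK targets Ets21C (2.94 ± 0.12), Pvf1 (2.40 ± 0.15), scaf (2.08 ± 0.14) and puc (1.90 ± 0.14), and the ligand genes upd1 (3.37 ± 0.16) and upd2 (3.34 ± 0.15), increased between the ages. The cuticle gene Cpr31A (-1.52 ± 0.11), the nuclear receptor gene Eip78C (-2.30 ± 0.16), Glut1 (-1.49 ± 0.16) and sens (-2.12 ± 0.14) decreased.

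The interaction was called for 2175 genes, 913 higher and 1262 lower, and 374 of them differed at least 2-fold. Of the 28 lists 7 were called higher and 6 lower, where higher means a larger difference at 116 h, and with an estimated correlation 3 of these calls held. For the JNK list 11 of 19 measured members rose and 2 fell (13 and 3 adjusted over the list alone), and for the JAK/STAT list 6 of 10 measured members rose and 1 fell (6 and 1 adjusted over the list alone), with adjusted p of 2.53e-07 and 1.15e-05. Innate immune genes were called higher (adjusted p = 0.00151), where 8 of 26 measured members rose and 1 fell (10 and 1 adjusted over the list alone), among them the NF-kappaB gene dl (0.83 ± 0.089), nec (1.24 ± 0.22) and Def (0.96 ± 0.24). Notum patterning genes were called lower (adjusted p = 0.0139, 0.351 with an estimated correlation), where 0 of 8 measured members rose and 5 fell (0 and 5 adjusted over the list alone), among them pnr (-1.16 ± 0.25), eyg (-0.78 ± 0.12) and bab1 (-0.84 ± 0.22). With the 3 tissue values as covariates the interaction was called for 1068 genes (530 higher and 538 lower), and the calls of pnr, bab1, mirr and Def ended.

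The differences at 92 h and 116 h shared members. At least 2-fold and called at both ages were 14 genes that were higher each time, against 0.97 for independent lists, and 6 that were lower each time, against 0.15. At this size 1 gene was higher at 92 h and lower at 116 h, and none was lower and then higher. Called at both ages at any size were 175 genes higher each time, against 36.8 for independent lists, 171 lower each time (46.7), 12 higher and then lower (55.6) and 20 lower and then higher (30.9). Ilp8, mthl8 and pinta belonged to the shared rises, with 2.29 and 2.72 at 116 h for mthl8 and pinta, and Obp46a, Gr64a, RpS21, RpS19b and Mis12 to the shared falls. Across the 11982 genes the differences correlated with r = 0.32 and rho = 0.23. Muscle transcripts were higher in avl-RNAi discs at both ages, so RNA of other tissues can add to the shared rises. The muscle gene Mlp60A was higher each time at the probe set used (1.12 and 1.69).

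Control discs between 92 h and 116 h showed how normal discs change as the larva nears pupariation. ImpE2, an ecdysone-inducible gene of discs, rose by 8.75 ± 0.36, from 4.62 ± 0.20, below the median of every array, to 13.37 ± 0.19 (mean ± SD, n = 3). Spn43Aa (5.76 ± 0.23), ana (5.11 ± 0.13), St2 (5.04 ± 0.15) and Cpr49Ac (4.78 ± 0.32) followed. The largest falls were the cuticle genes Cpr47Ec (-3.39 ± 0.23) and Cpr47Eg (-2.86 ± 0.23), IM33 (-3.36 ± 0.51), Jhbp7 (-3.19 ± 0.22) and Nplp2 (-2.94 ± 0.33). Ilp8 fell as well (-1.23 ± 0.16), and chinmo went from 9.51 ± 0.026 to 6.80 ± 0.14 (-2.71 ± 0.11).

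Patterning and differentiation lists rose in control discs with age. For wing pouch and hinge patterning 18 of 31 measured members rose and 2 fell (20 and 2 adjusted over the list alone, camera adjusted p = 4.02e-06, 0.18 with an estimated correlation). Doc2 rose by 1.14 ± 0.094, inv by 0.67 ± 0.088 and en by 0.54 ± 0.069. For Notch targets and proneural genes 14 of 21 measured members rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 3.42e-07, 0.127 with an estimated correlation), with sens at 2.29 ± 0.096. For ecdysone response genes 12 of 26 measured members rose and 2 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.000298, 0.127 with an estimated correlation), with ImpE3 at 3.88 ± 0.18 and Eip78C at 2.26 ± 0.11. For notum patterning 6 rose and 0 fell of 8 (6 and 0 adjusted over the list alone, camera adjusted p = 0.00146, 0.186 with an estimated correlation). For myoblast markers 9 rose and 2 fell of 14 (10 and 3 adjusted over the list alone, camera adjusted p = 0.00146, 0.127 with an estimated correlation). For glycolysis 5 rose and 0 fell of 13 (7 and 0 adjusted over the list alone, camera adjusted p = 0.00125, 0.127 with an estimated correlation). Glut1 rose by 1.31 ± 0.11 and the myoblast gene Him by 1.65 ± 0.13. Endosomal genes (adjusted p = 0.014, 0.127 with an estimated correlation) and apoptosis genes (adjusted p = 0.0302, 0.186 with an estimated correlation) were called higher too, with Lamp1 at 0.43 ± 0.05 and the initiator caspase gene Dronc at 0.50 ± 0.058.

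Respiration, cell cycle and JAK/STAT lists fell. For oxidative phosphorylation 0 of 71 measured members rose and 46 fell (0 and 46 adjusted over the list alone, camera adjusted p = 1.49e-13, 0.127 with an estimated correlation), by modest amounts such as COX5B at -0.55 ± 0.063. For cell cycle and DNA replication 2 of 36 measured members rose and 23 fell (2 and 24 adjusted over the list alone, camera adjusted p = 1.43e-07, 0.158 with an estimated correlation), with the replication genes Orc2 (-0.63 ± 0.055), Cdc6 (-0.60 ± 0.065) and Mcm5 (-0.54 ± 0.055). For JAK/STAT 0 of 10 measured members rose and 3 fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.0203, 0.127 with an estimated correlation), these being chinmo, upd1 (-1.15 ± 0.11) and ken (-0.81 ± 0.082).

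In all, 3232 genes were called between the ages in control discs, 1584 higher and 1648 lower at 116 h, with 218 at least 2-fold higher and 155 at least 2-fold lower. Gut transcripts differed widely within both control groups, and muscle transcripts were lower at 116 h. With the 3 tissue values as covariates 257 genes were called, of which most were now higher (166 higher and 91 lower, or 132 and 49 at least 2-fold), and the median standard error rose from 0.074 to 0.18; ImpE2, Spn43Aa, sens and chinmo stayed called, whereas the calls of Ilp8, IM33, Nplp2, Glut1, Him, upd1, ken, en, inv, Mcm5, COX5B, Lamp1 and Dronc ended.

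In avl-RNAi discs the same interval brought rises of Ilp8 and of the ligand gene upd2, among others. TwdlE, a cuticle gene of the Tweedle family, rose by 6.11 ± 0.18, followed by Tdc1 (4.57 ± 0.12), the lipid phosphatase gene wun2 (3.55 ± 0.12), upd2 (3.34 ± 0.11) and Ilp8 (3.30 ± 0.16). The largest falls were Cpr47Eg (-4.70 ± 0.23), Acbp4 (-4.64 ± 1.29, not called without avl-RNAi 92 h replicate 1, -3.82), CAH9 (-4.10 ± 0.15), Lcp65Ag3 (-3.89 ± 0.19) and the digestive protease gene Jon25Bi (-3.21 ± 1.09). The call of Jon25Bi ended when any array but avl-RNAi 92 h replicate 2 was left out (-2.54 to -3.39), and gut transcripts as a whole fell over the same interval. Of the 28 lists 12 were called higher and 2 lower. The JNK list rose (adjusted p = 1.47e-08), where 15 of 19 measured members rose and 2 fell (15 and 2 adjusted over the list alone), with puc at 2.00 ± 0.10. Cell cycle genes fell as in control discs, where 1 of 36 measured members rose and 30 fell (1 and 30 adjusted over the list alone, camera adjusted p = 1.69e-11, 0.11 with an estimated correlation). Oxidative phosphorylation fell too, where 1 of 71 measured members rose and 49 fell (1 and 51 adjusted over the list alone, camera adjusted p = 1.49e-13, 0.11 with an estimated correlation).

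The other lists called higher in this interval lost the call with an estimated correlation. For Notch targets and proneural genes 7 rose and 1 fell of 21 (9 and 1 adjusted over the list alone, camera adjusted p = 0.00535, 0.318 with an estimated correlation), and for ecdysone response genes 11 rose and 3 fell of 26 (12 and 3 adjusted over the list alone, camera adjusted p = 0.019, 0.191 with an estimated correlation). The others were JAK/STAT (adjusted p = 0.00255, 0.0613 with an estimated correlation), secreted signals (0.00254, 0.0643), extracellular matrix (0.00394, 0.191), tracheal markers (0.00394, 0.191) and innate immune genes (0.0144, 0.11). Myoblast markers (adjusted p = 0.0144, 0.113 with an estimated correlation), early larval factors (0.0145, 0.141), apoptosis (0.0312, 0.191) and endosomal genes (0.0312, 0.162) completed them.

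Between 92 h and 116 h 4247 genes were called in avl-RNAi discs, 1773 higher and 2474 lower, with 245 at least 2-fold higher and 129 at least 2-fold lower. Gut and muscle transcripts were lower at 116 h than at 92 h in these discs. With the 3 tissue values as covariates 2002 genes were called, 836 higher and 1166 lower. Across genes the ageing differences of control and avl-RNAi discs correlated with r = 0.49 and rho = 0.43.

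Genes that age in control discs were followed in avl-RNAi discs. Of the 218 that rose at least 2-fold in control discs, 121 rose in avl-RNAi discs from 92 h to 116 h, 16 fell and 81 were not called. The median rise was 1.48 in control and 0.50 in avl-RNAi discs, and the interaction was called lower for 152 of them and higher for 7. Of the 155 that fell at least 2-fold, 90 fell in avl-RNAi discs and 21 rose, with medians of -1.37 and -0.76, and the interaction was called in the other direction from the fall for 73. ImpE2 reached 7.85 ± 0.52 in avl-RNAi discs at 116 h, against 13.37 ± 0.19 in controls. The sensory organ gene sens stayed at 3.94 ± 0.044, below the median of every array, against 6.19 ± 0.23 in controls. The genes were chosen on the control difference that is part of the interaction, which by itself favours smaller changes in the other genotype. With the 3 tissue values as covariates 108 genes, in place of 225, had an interaction called against the control's direction, among 181 in place of 373.

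**Figure D4:**
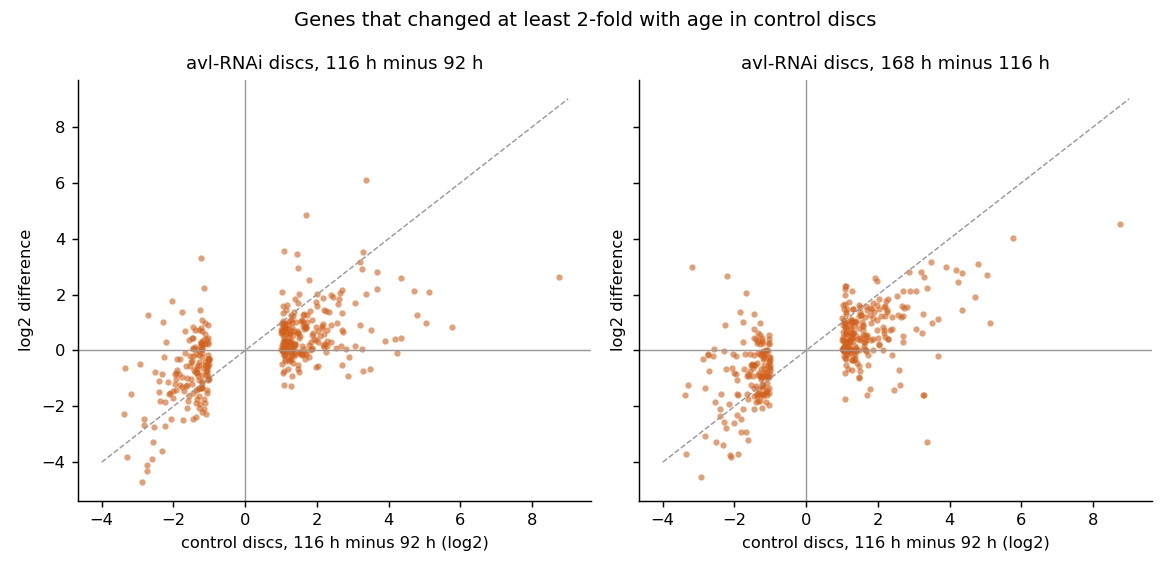
Log2 difference in avl-RNAi discs, from 92 h to 116 h (left) and from 116 h to 168 h (right), against that in control discs from 92 h to 116 h, for the 373 genes that changed at least 2-fold in control discs (dashed line, equal change). The medians of the 218 control risers were 0.50 and 0.63 in avl-RNAi discs, against 1.48 in control discs.

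Only avl-RNAi discs were sampled at 168 h, so this interval has no control of the same age. From 116 h to 168 h ImpE2 (4.53 ± 0.36) and Spn43Aa (4.02 ± 0.23) rose in avl-RNAi discs, together with the cuticle gene Cpr64Ac (4.62 ± 0.088), the ecdysone-inactivating cytochrome gene Cyp18a1 (3.47 ± 0.14) and the amino acid transporter gene path (3.23 ± 0.13). Ilp8 rose slightly further (0.46 ± 0.16, adjusted p = 0.0457), a call that ended without any 1 of the arrays at 168 h and without avl-RNAi 116 h replicate 2 or 3 (0.35 to 0.49), while puc (-0.77 ± 0.10) and upd2 (-1.59 ± 0.11) fell. The activin ligand gene Actbeta (2.96 ± 0.099) and the FGF ligand gene bnl (1.41 ± 0.069, with probe sets from 0.11 to 1.41) rose. The largest falls were Nplp2 (-4.53 ± 0.33), the muscle genes Mlp60A (-3.83 ± 0.18, with probe sets from -3.83 to 0.068) and Mlc1 (-3.75 ± 0.26), IM33 (-3.69 ± 0.51) and the clotting gene fon (-3.40 ± 0.66), and muscle and fat body transcripts were at their lowest at 168 h.

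Wing pouch and hinge patterning genes rose late in avl-RNAi discs, where 18 of 31 measured members rose and 3 fell (21 and 3 adjusted over the list alone, camera adjusted p = 1.07e-06, 0.602 with an estimated correlation). The POU gene pdm2 was at 1.65 ± 0.091 and Doc2 at 1.49 ± 0.094. Cell cycle genes were called higher, where 14 of 36 measured members rose and 2 fell (15 and 3 adjusted over the list alone, camera adjusted p = 0.0058, 0.602 with an estimated correlation). So were junction and polarity genes, where 15 of 32 measured members rose and 3 fell (19 and 3 adjusted over the list alone, camera adjusted p = 0.00548, 0.602 with an estimated correlation). In all, 3237 genes were called, 1854 higher and 1383 lower at 168 h, with 166 at least 2-fold higher and 203 at least 2-fold lower. Of the 218 control risers 135 rose in this interval and 20 fell, and of the 155 control fallers 94 fell and 18 rose. At least 2-fold in both were 81 risers, against 3.02 for independent lists, and 61 fallers, against 2.63. The fallers include muscle and fat body genes such as Mlc1 and Mlp60A, and their median late change was -0.80, or -0.30 with the 3 tissue values as covariates, against 0.63 and 0.52 for the risers. With the 3 tissue values as covariates 16 genes were called, all at least 2-fold, 15 higher and 1 lower; these values shifted with age, and the median standard error rose from 0.074 to 0.26. The calls of ImpE2, Spn43Aa, path, Nplp2, IM33, puc and Doc2 ended with their direction kept, and that of fon turned to 0.32.

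Against the oldest controls, at 116 h, avl-RNAi discs at 168 h still had far more Ilp8 (6.48 ± 0.16), together with Jhbp7 (5.22 ± 0.22), Osi15 (5.11 ± 0.19), Cpr64Ac (4.75 ± 0.088) and GstE6 (4.09 ± 0.11). The largest falls were the glue protein gene Sgs7 (-2.55 ± 0.49), the homeobox gene Optix (-2.52 ± 0.18), Mlc1 (-2.42 ± 0.26), Cyp310a1 (-2.42 ± 0.26) and ana (-2.39 ± 0.13). For the JNK list 14 of 19 measured members rose and 2 fell (14 and 2 adjusted over the list alone, camera adjusted p = 1.4e-09). For JAK/STAT 7 rose and 0 fell of 10 (7 and 0 adjusted over the list alone, camera adjusted p = 8.57e-08), and for secreted signals 14 rose and 4 fell of 26 (14 and 4 adjusted over the list alone, camera adjusted p = 4.58e-07). For Notch targets and proneural genes 0 of 21 measured members rose and 16 fell (1 and 17 adjusted over the list alone, camera adjusted p = 6.6e-08, 0.169 with an estimated correlation), and the wing regulators vg and Dll were at -1.17 ± 0.095 and -1.51 ± 0.13. In all, 3070 genes were called, 1432 higher and 1638 lower, with 206 at least 2-fold higher and 88 at least 2-fold lower. Genotype and age differed together here, so this comparison alone cannot assign a difference to either; with age equal, at 116 h, Ilp8 and GstE6 were already at 6.02 and 3.78. With the 3 tissue values as covariates 820 genes were called, of which most were now higher (486 higher and 334 lower).

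With an estimated correlation, the list calls that held were JNK, JAK/STAT and glutathione transferases at 116 h, JNK, JAK/STAT and innate immune genes in the interaction, JNK in avl-RNAi discs from 92 h to 116 h, and JNK, JAK/STAT and secreted signals at 168 h against control. No list call held with it at 92 h, in control ageing or in avl-RNAi discs from 116 h to 168 h.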

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

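The comparison of the later interval with random lists, the test of the chromosomes, the interaction of the genes higher or lower at 92 h and all tests with tissue transcripts were chosen only after the result was seen. The results below stand out because the avl-RNAi difference itself differed between 92 h and 116 h by the interaction test, or because a signal lay in probe sets that the report does not use.

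The difference between avl-RNAi and control discs grew or turned positive from 92 h to 116 h for JNK, JAK/STAT and other genes. Interaction values were 4.53 for Ilp8, 1.90 for puc, 2.94 for Ets21C, 2.40 for Pvf1, 2.08 for scaf, 0.62 for Traf4, 3.37 for upd1, 3.34 for upd2, 1.24 for ken and 3.99 for chinmo. They were 4.65 for Tdc1, 3.69 for flap, 3.83 for Osi14, 3.40 for Rcd2, 3.28 for Ude, 0.46 for mthl8, 1.19 for pinta, 0.88 for Imp, 0.73 for dpn and 0.46 for Sox15. Glutathione transferase and metallothionein genes gave 3.15 (GstE6), 1.48 (GstE1), 0.79 (GstO1) and 1.28 (MtnA). Matrix and tracheal genes gave 3.36 (Tig), 1.52 (Swim), 0.74 (trol), 0.62 (SPARC), 0.35 (dlp), 0.52 (serp), 0.57 (Gasp) and 0.58 (verm).

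Genes that were lower at 92 h and less so, or no longer, at 116 h gave 1.25 (Mtk), 0.70 (PGRP-SB1), 1.01 (DptB), 0.96 (Def), 1.55 (Ktch) and 0.57 (Gr64f), whereas RpS19b gave -0.54. The rises of larval cuticle genes and of l(3)mbn at 92 h shrank or ended, with -2.39 for Lcp65Ac, -1.83 for Cpr47Eg, -1.60 for Lcp65Ae, -1.29 for Lcp65Ag3 and -1.21 for l(3)mbn. Ance gave -1.02, ush -0.45 and Ppn -0.91; Ppn was not called at 92 h, ush was not called at 116 h, and the calls of Ance and ush at 92 h ended without control replicate 3.

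Other large decreases were -6.12 for ImpE2, -3.55 for ImpE3, -4.93 for Spn43Aa, -4.32 for Spn100A, -4.04 for St2, -3.77 for nebu, -3.78 for wbl, -3.04 for ana, -3.52 for Cpr49Ac and -2.77 for Cpr78E. ImpE2 and ImpE3 belong to the ecdysone response list, which was not called in the interaction (adjusted p = 0.0896). Patterning genes gave -1.29 (Doc2), -0.84 (Doc3), -1.33 (dve), -2.12 (sens), -0.77 (sc), -0.60 (ase), -0.67 (Tom) and -0.39 (Brd). The JNK list member wgn moved against its list (-0.66). Cell cycle and glycolysis genes gave -0.51 (E2f2), -0.36 (Cdk4), -0.25 (borr), -1.49 (Glut1) and -0.48 (Pfk).

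Median interaction values of the called lists were 0.41 for JNK, 0.53 for JAK/STAT, 0.18 for secreted signals, 0.21 for innate immune genes, 0.11 for glutathione transferases, 0.072 for early larval factors and 0.13 for tracheal markers. They were -0.31 for wing pouch and hinge patterning, -0.61 for notum patterning, -0.39 for Notch targets and proneural genes, -0.12 for cell cycle genes, -0.11 for oxidative phosphorylation and -0.16 for glycolysis. With an estimated correlation only the calls of JNK, JAK/STAT and innate immune genes held, and the adjusted p of the others ran from 0.082 to 0.575. Among 5122 probe sets with no gene name of their own, 9 were at least 2-fold higher in avl-RNAi discs at 92 h and 43 at 116 h.

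Genes that rose in control discs and rose less in avl-RNAi discs (152 genes, median interaction -1.43) were weighed first. RNA of gut, muscle or fat body is argued against as the whole cause, since the median was -1.36 with gut, muscle and fat body values as covariates, and so is control 116 h replicate 2, since it was -1.37 without that array. A later onset of the same programme is a candidate explanation: the 218 genes that rose in control discs had a median rise of 0.63 from 116 h to 168 h in avl-RNAi discs, where the highest median of 10000 random lists matched on mean expression was 0.079. These 218 genes already exceeded such lists from 92 h to 116 h in avl-RNAi discs (median 0.50, highest random median 0.070). The genes that fell in control discs also lay outside them from 116 h to 168 h (median -0.80, lowest random median -0.064). Random lists hold unrelated genes, so exceeding them does not single out a later onset. The 218 genes hold more than the 152 that rose less, which were not tested apart. From 116 h to 168 h 135 of the 218 rose and 20 fell. The gene sens lay between 4.19 and 4.45 in avl-RNAi discs at 168 h. In control discs at 116 h it lay between 5.92 and 6.36. With the covariates the late median was 0.52 for the risers and -0.30 for the fallers. Age and genotype are not crossed at 168 h, so a response of old discs to the knockdown stays open, untested, as does RNA of tissues not scored.

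The 38 genes at least 2-fold higher in avl-RNAi discs at 92 h (median 1.22) included 10 cuticle genes. RNA of gut, muscle or fat body is argued against as the whole cause, since their median was 1.33 with the covariates and 23 stayed called. The interaction passed Bonferroni adjustment over all tested genes, which holds however genes are chosen, for 7 of them, among them Ilp8 and Lcp65Ac, which argues against the same fixed stock difference for every gene of the set. Others, such as Lcp65Ae and Cpr47Eg, had the interaction called without passing that adjustment, which leaves a fixed stock difference undecided for them. For genes without a called interaction a fixed stock difference stays open. The interaction was called for 24 of the 38 genes, and its median over the set was -0.65. Choosing genes on their difference at 92 h lowers this median by itself. With genes chosen without the arrays that gave this difference the middle of 9 medians was -0.40 (range -0.44 to 0.063). Pairs with control replicate 2 gave -0.056 to 0.063 and the other pairs -0.44 to -0.24, so the decrease depended on that array. The pairs share arrays, so these medians are not independent. A shift of developmental stage between the genotypes at 92 h and RNA of cuticle-forming tissue such as epidermis and trachea stay open, untested.

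The 11 genes at least 2-fold lower at 92 h (median -1.38) had a median of -1.33 at 116 h, but 5 of them had the interaction called, among them Ktch (0.063 at 116 h), Mtk (-0.26) and CG11893 (1.0, chosen after its values were seen). RNA of gut, muscle or fat body is argued against as the whole cause, since the median was -1.48 with the covariates and 7 stayed called, and RNA of other tissues stays open, untested. Of these only 1, Ktch, passed Bonferroni adjustment, which argues against the same fixed stock difference for every gene of the set. CG11893, Mtk, Gr64f (interaction 0.57) and RpS19b (-0.54) had the interaction called without passing that adjustment. Stock and construct go together. For genes without a called interaction, such as RpS21 and Mis12, a fixed stock difference and a constant effect of the RNAi construct therefore cannot be told apart. Genes on chromosome 3 made up 48.2% of the called genes at 92 h and 44.5% of the others (Fisher's exact p = 0.0997), with the arms apart (3L 27.5% and 19.3%, adjusted p = 8.89e-05; 3R 20.7% and 25.2%, adjusted p = 0.118), which did not settle it.

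Splits of 6 arrays into groups of 3 are too few (10, the real one included, as large in 1) for a share under 0.05. The called genes were 537 at 92 h and 3794 at 116 h, with 0 in the highest other split, 3232 in control ageing, with 12, and 4247 in avl-RNAi ageing, with 1. They were 3237 from 116 h to 168 h and 3070 at 168 h against control, with 0. At least 2-fold were 49, 469, 374, 369 and 294 genes, with 0 in the highest other split, and 373 in control ageing, with 12.

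For the interaction, 7 of 100 splits called at least the real 2175 genes, with 2411 as the highest other, and 15 of 100 gave at least the real 374 genes at 2-fold, with 507. For the 225 ageing genes that differed 6 of 100 did, with 244 as the highest other. Chance is not excluded by these counts. All of the other splits as large (6, 14 and 5) left the 116 h arrays in their real groups, and so kept the large difference at 116 h, which 14 of the drawn splits did; the highest count without that was 25, 17 and 4. The 20 genes shared at 2-fold by 92 h and 116 h were reached by the real split alone, 1 of 100, with 0 as the highest other. Because the other splits at either age gave no gene at 2-fold, this outcome was fixed in advance and decides nothing.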

How the results depend on the processing

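The settings with tissue transcripts as covariates or without both unusual control arrays were chosen only after the result was seen; the others were planned. Of the values of named genes 3682 kept their side of the threshold in other settings, 166 lost and 17 gained a call, and 1 reversed. Without 1 array 2227 kept their side, 73 lost and 4 gained a call. Of the list results 2539 kept their side, 121 lost and 84 gained a call, and without 1 array 1288, 29 and 27. Direction was compared only for results called in the main fit, so those called in neither fit count as kept whatever their sign.

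With the gut, muscle and fat body values as covariates, called genes were 135 at 92 h, 688 at 116 h, 1068 in the interaction and 257 in control ageing (181 at least 2-fold). They were 2002 in avl-RNAi ageing, 16 from 116 h to 168 h (16 at least 2-fold) and 820 at 168 h against control, and 108 ageing genes differed. The share of higher genes rose, to 64.4% at 92 h, 57.6% at 116 h, 64.6% in control ageing (72.9% at least 2-fold), 93.8% from 116 h to 168 h (the same at least 2-fold) and 59.3% at 168 h against control. The median standard error rose from 0.074 to 0.10 at 92 h and to 0.26 from 116 h to 168 h, since these values differ between the groups. The value of fon from 116 h to 168 h reversed, to 0.32; the cause was not tested. Jon25Bi, Mlc1 and Mlp60A are part of these values, so their own results with the covariates say nothing.

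At 92 h called genes were 345 with the compared groups only, which leaves fewer degrees of freedom, 257 without both unusual control arrays and 225 at adjusted p under 0.01. They were 288 to 390 without 1 array (351 without avl-RNAi replicate 2, and 288, 349 and 290 without control replicates 1, 2 and 3). At least 2-fold were 26 without the lowest 50% of genes by mean value, where fewer genes were tested. At adjusted p under 0.01 called genes were 1231 in the interaction, 2091 from 116 h to 168 h and 2041 at 168 h against control. With the replicate block, which the arrays do not bear out as a pairing throughout, 488 were called at 92 h and 3726 at 116 h.

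Called lists at 92 h were 3 without the lowest 50% of genes, 3 with the 3 covariates, 0 with an estimated correlation, and 3 to 7 without 1 array (3 without control replicate 1). With an estimated correlation they were 3 at 116 h, 3 in the interaction, 0 in control ageing, 1 in avl-RNAi ageing, 0 from 116 h to 168 h and 3 at 168 h against control. With fry, which tests a shift of a list in 1 direction without comparing it with other genes, they were 20 at 116 h, 20 in control ageing, 16 from 116 h to 168 h and 17 at 168 h against control. Signal over background limits transcripts near the floor of the arrays; no background values were analysed here.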

Other observations

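The test of single chromosome arms and the choice of CG5664 were made only after the result was seen. Genes on 3L made up 147 of the 535 genes called at 92 h that had a position, with an odds ratio of 1.58 and adjusted p = 8.89e-05 by Fisher's exact test over 11 tests; for 3R it was 111 of 535, with an odds ratio of 0.777 and adjusted p = 0.118. At 116 h genes on 3L made up 20.6% and 19.3% (Fisher's exact p = 0.113). These tests treat genes as independent, so genes of an arm that change together can make the p-values too small. CG5664, a neighbour of Syx7 on 3L, was at -0.97 ± 0.052 at 92 h, -0.75 ± 0.052 at 116 h and -0.68 ± 0.052 at 168 h against control at 116 h.

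The largest fall among probe sets with no gene name was -2.66 at 92 h and, for the same probe set, -3.48 at 116 h. The largest rises at 116 h were 4.26 and 4.25. These were chosen after their values were seen. At 116 h 43 such probe sets were at least 2-fold higher and 30 lower.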
